A study of Mus musculus with 4 samples.

How the data were processed

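Chromatin bound by the transcription factor ATF4 was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse regulatory T cells. These are CD4+ T cells that restrain immune responses, and they were enriched here as CD4+CD25+ cells. Per the labels, 2 samples were ATF4 immunoprecipitates and 2 were inputs, with replicates 1 and 2 in each group. Per the labels, cells were fixed with 1% formaldehyde for 10 min, and 1% of the sheared material was kept as input. The sample labels name spleen as the tissue, while the series' design names spleen and lymph nodes.

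The deposited data used here were 1 peak list for the whole series. Per the submitters' processing notes, the tools were Trim Galore, Bowtie2, MACS2 and deepTools, and the genome build was mm10. Their versions are not given in the sources used here. The peak names carry the title of a single Bowtie2 alignment. Whether the replicates were pooled, and how the inputs entered the peak calls, is not given in the sources used here, and neither is whether the replicates came from separate mice. Each peak has a fold enrichment at its summit, a −log10 p, a −log10 q and a score, all of them the authors' deposited values and in the layout that MACS2 writes. The score equalled the −log10 q multiplied by 10 and rounded down in 4543 of 4544 peaks. The annotation class, the assigned gene and the distance to the transcription start site (TSS) are also the authors' deposited values, in the layout of ChIPseeker. Peak starts were counted from 0 in the deposited list and were raised by 1. With that shift, the deposited distance to the TSS was recovered in 4544 of 4544 peaks. Peak numbers ran to 4549, and 5 of them were not in the list used here.

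Fold enrichment was used only within the list, to describe, rank, filter and compare peaks. The list gives no values per sample and no read totals, so the depth of each sample is unknown and no value has a replicate error. Peaks and genes are not replicates of the experiment. P-values and intervals over them cover counting error within this list only and say nothing of how peaks would vary between mice.

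Gene names and types came from a RefSeq gene table of assembly GRCm38.p6, in which all 3634 gene symbols of the list were found. The background for gene lists was the 21887 protein-coding genes placed on chromosomes 1 to 19, X and Y. It includes genes that are silent in T cells. Before the data were examined, 26 gene lists and the rule for named genes were fixed. Of the lists, 735 of 736 entries matched a background gene. Ahsp did not match, and Pycr3 matched by synonym. Of 677 distinct list genes, 56 stood in more than 1 list.

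A gene was counted as having a promoter peak when at least 1 peak of the authors' Promoter class was assigned to it, which reached 2.97 kb from the TSS. Each list was compared with all other background genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 26 lists and a threshold of 0.05. Shares have exact Clopper-Pearson intervals at 95%. Fold enrichments were compared by two-sided permutation tests of the difference in medians, with 100000 permutations, for which the smallest p is 1e-05. For comparisons of gene lists, the strongest promoter peak of each background gene was taken, and lists with fewer than 4 such genes were not tested. The comparison of Promoter with Distal Intergenic peaks used all peaks of those classes. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

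The tests were tried on simulated data. Lists drawn at 4 times the base rate of promoter peaks were called in 270 of 300 tests, and lists at the base rate in 11 of 1000. A doubled strength of 30 peaks was called in 40 of 40 sets, and an unchanged strength in 3 of 40. Weaker enrichment, smaller differences in strength and strength tests of fewer than 30 genes were not simulated. These rates therefore do not give the power for the lists that were not called.

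By that rule, the genes to be named were the genes of the 20 strongest peaks by fold enrichment, up to 4 members of each list with the strongest promoter peaks, the genes of the 5 strongest Distal Intergenic and the 5 strongest Intron peaks, and a fixed set. The fixed set was Atf4, Foxp3, Il2ra, Ctla4, Ikzf2, Icos, Il10, Tgfb1, Prdm1, Batf, Irf4, Gata3, Il1rl1, Pparg, Klrg1, Asns, Trib3, Ddit3, Chac1, Sesn2, Slc7a11, Psat1, Phgdh, Mthfd2, Atf3, Atf5 and Cebpb. Genes outside the rule are said to have been chosen after their values were seen.

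Tests of technical explanations in the closing section were rewritten or dropped after results had been seen, and what changed is stated there. Alternatives covered the strength and significance thresholds, the definition of a promoter, the assignment of peaks to genes, neighbouring peaks and genes shared between lists. Sequence motifs were not analysed here, since no genome sequence was used. The placement of peaks against random positions was not analysed here either.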

Results

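ATF4 is a basic leucine zipper factor that activates genes of amino acid supply and of the stress response. To find where it lies in the genome of regulatory T cells, ATF4 ChIP-seq was done on CD4+CD25+ cells in 2 samples, with 2 input samples. The deposited result is 1 list of 4544 peaks on build mm10, and every fold enrichment and −log10 q below is the authors' own. Fold enrichment ranged from 1.17 to 43.8 with a median of 3.30, and −log10 q had a median of 5.71. Of the listed peaks, 129 had a q over 0.05 and 1049 a −log10 q under 3. Peaks had a median width of 261 bp. There are no values per replicate, so no value has a replicate error, and the depth of the samples is unknown. Intervals cover counting error only.

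The peak with the highest fold enrichment, 43.8, lay on chromosome 8 at 121850877 to 121851473. It was assigned to the promoter of the long noncoding RNA gene Gm26812, 392 bp from the TSS of the assigned transcript. It lay inside the span of that gene. Next came the promoter of Chac1, which encodes a glutathione-degrading enzyme, at 38.4 (chromosome 2, 119350792 to 119351285). A distal peak 19.1 kb from the TSS of Slc7a1, a cationic amino acid transporter, reached 29.8. A distal peak 4.59 kb from Bmf, which encodes a pro-apoptotic BH3-only protein, reached 28.3. Promoters of Gtf2a1, a general transcription factor gene, the histone gene H4c14 and the eIF2α phosphatase subunit gene Ppp1r15b had peaks at 28.1, 27.2 and 27.1. The alanyl-tRNA synthetase gene Aars followed at 25.3, the ER stress gene Herpud1 at 24.1 and the stress-induced factor gene Ddit3 at 22.8. The peak at 22.3 assigned to S100pbp also overlapped the low-coordinate end of the tyrosyl-tRNA synthetase gene Yars (chromosome 4, 129189663 to 129190136), a gene chosen after its values were seen. Among the 20 strongest peaks were also those at Gm22068 at 20.4, Gm22513 at 19.6, LOC115488065 at 19.3, Rnu3b2 at 19.0 and Rnu3b1 at 18.2, which the gene table classes as snRNA genes.

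Most peaks lay at promoters. Of 4544 peaks, 3375 were of the Promoter class, which is 74.3% (95% exact interval 73.0 to 75.5). Distal Intergenic peaks made up 11.5% (10.6 to 12.5), Intron peaks 10.2% (9.32 to 11.1), 3′ UTR peaks 1.96% (1.58 to 2.40) and Exon peaks 1.5% (1.16 to 1.89). There were 16 Downstream and 9 5′ UTR peaks. In all, 2033 peaks overlapped the annotated TSS, or 44.7% (43.3 to 46.2). At least 1 promoter peak was assigned to 2476 of the 21887 background genes, or 11.3%.

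**Figure D1:**
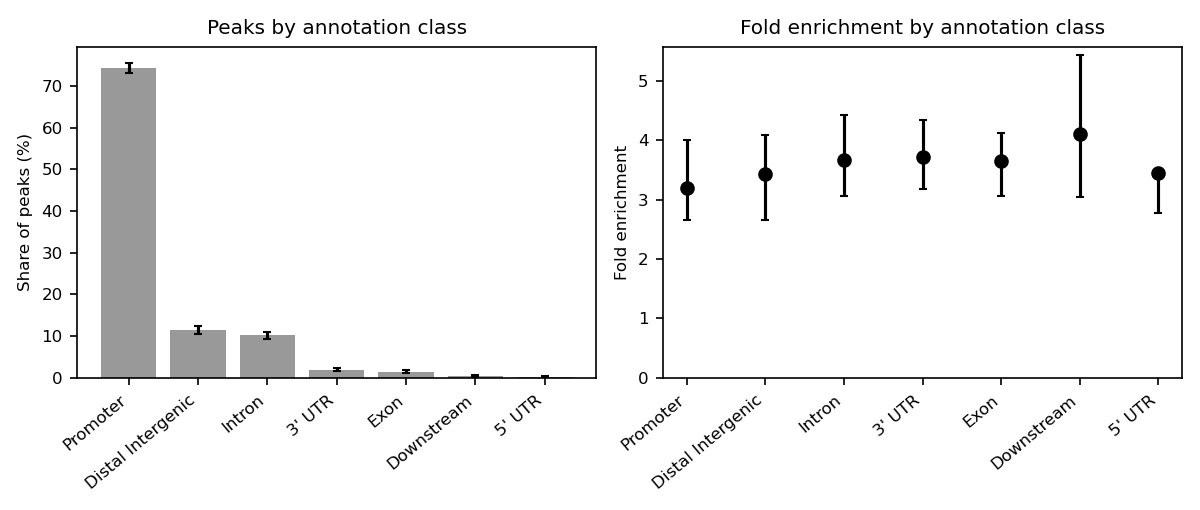
Left, share of the 4544 peaks in each annotation class (percent), with 95% exact intervals. Right, median fold enrichment of each class with its quartiles as bars; the Promoter median was 3.19 and the Distal Intergenic median 3.43.

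Distal peaks had the higher median fold enrichment. It was 3.19 over 3375 Promoter peaks and 3.43 over 524 Distal Intergenic peaks, a promoter minus distal difference of −0.247 (permutation test, p = 7e-05). Peaks were taken to lie over repeated sequence when their gene had at least 10 peaks or they lay on unplaced or unlocalised sequences. No repeat annotation was used. Without the 73 such peaks of the list, the difference was −0.388 (permutation test, p = 1e-05, the smallest possible). The sign turned with the measure: by −log10 q the Promoter median was 6.45 and the Distal Intergenic median 4.14 (permutation test, p = 1e-05, the smallest possible). The upper end was not tested: 10.5% of Promoter peaks and 6.49% of Distal Intergenic peaks had a fold enrichment of at least 5.34, as the 455 strongest peaks of the list did. After Slc7a1 and Bmf, the strongest distal peaks were assigned to 1810013L24Rik at 13.3, Ccdc9 at 9.87 and Gm31473 at 9.42. The strongest Intron peaks were assigned to Gm35730 at 25.8, Olfr266 at 24.7, Slc7a5 at 24.0, Nfatc1 at 14.3 and Mir7001 at 14.2. That of Gm35730 lay inside the span of the phosphofructokinase gene Pfkp, and that of Nfatc1, 25.1 kb from its TSS, lay inside Atp9b.

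Canonical ATF4 targets had the highest share of genes with a promoter peak among the 26 lists. Of 40 canonical ATF4 targets, 30 had a promoter peak, or 75% (58.8 to 87.3), against 11.2% of other genes (odds ratio 23.8, adjusted p = 2.4e-19, Fisher's exact test). The other genes include ones that are silent in T cells, since no expression data were used here. The strongest were Chac1, Herpud1, Ddit3 and the translation repressor gene Eif4ebp1 at 13.1. Asparagine synthetase gene Asns had 10.1, the pseudokinase gene Trib3 9.18, Atf5 7.85, the serine synthesis genes Psat1 and Phgdh 7.69 and 3.97, and the folate enzyme gene Mthfd2 12.5. The Atf5 peak lay 2355 bp from its TSS and overlapped the span of Nup62, a gene chosen after its values were seen. No peak was assigned to Sesn2, Slc7a11, Atf3 or Cebpb. A peak of 6.29 assigned to A530013C23Rik, chosen after its values were seen, lay inside the span of Cebpb, 134 bp from an end. Atf4 itself had 1 promoter peak at 3.22 (chromosome 15, 80255441 to 80256133).

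Aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, had promoter peaks at 13 of 20 genes, or 65.0% (40.8 to 84.6; odds ratio 14.6, adjusted p = 9.0e-08, Fisher's exact test). Aars, Sars at 20.0, Iars at 15.6 and Gars at 14.4 led the list by assigned promoter peak. Yars counted as having none, since the peak at 22.3 over one of its ends was assigned to S100pbp. Amino acid transporters had them at 12 of 32 genes (odds ratio 4.72, exact test, adjusted p = 2.85e-04), among them Slc7a1 at 10.0, Slc38a2 at 8.54, Slc1a4 at 8.34 and Slc3a2 at 5.98. Other amino acid enzymes had them at 13 of 27 (odds ratio 7.31, exact test, adjusted p = 6.75e-06), among them Asns, Got1 at 7.13 and Gpt2 at 6.77. Serine, glycine and folate metabolism had them at 8 of 24 (odds ratio 3.93, exact test, adjusted p = 0.0080), led by Mthfd2, Shmt2 at 9.35, Psat1 and Mthfd1l at 6.16. With genes of more than 1 list left out, the call of this last list ended (11.8%, exact test, adjusted p = 1.00, from 9.7e-05 to 1.00 over the alternatives).

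Canonical targets also had stronger promoter peaks than other genes. Their median fold enrichment was 6.99 over 30 genes (quartiles 5.68 and 9.88) against 3.24 over 2446 other genes (quartiles 2.69 and 4.02), a difference of 3.76 (permutation test, p = 1e-05, the smallest possible). Of the 40 targets, 23 had a promoter peak among the 455 strongest peaks (exact test, adjusted p = 2.6e-33). Of the 20 lists with enough genes, 6 had stronger promoter peaks than other genes after adjustment and 0 weaker peaks. These were the canonical targets, tRNA synthetases at a median of 8.66, other amino acid enzymes at 5.76, serine and folate genes at 5.38, transporters at 5.07 and basic leucine zipper factors at 4.32. With genes of more than 1 list left out, 3 of 18 lists did, and the calls for transporters and other amino acid enzymes ended (adjusted p = 0.10 and 0.13, permutation tests). The serine and folate list was not tested there, since 2 of its 17 genes left had a promoter peak. By −log10 q, 8 of 20 lists did, with adjusted p = 0.038 for transporters and 0.0011 for other amino acid enzymes (permutation tests).

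**Figure D2:**
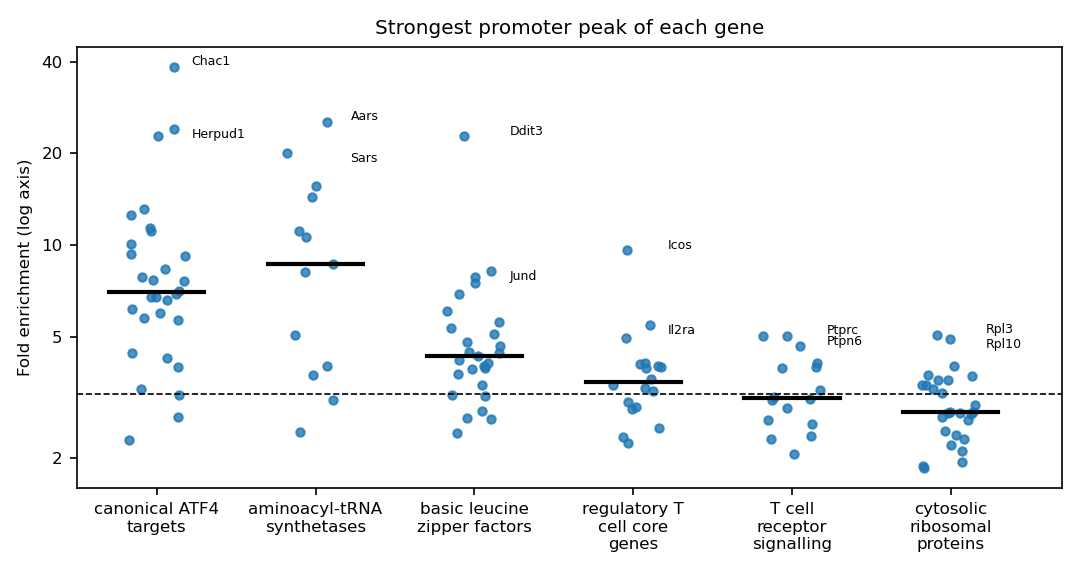
Fold enrichment (log axis) of the strongest promoter peak of each gene in 6 lists; each point is a gene, horizontal bars are list medians and the dashed line is the median of 3.24 over genes other than canonical targets. Canonical targets had a median of 6.99 and regulatory T cell core genes one of 3.56.

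Core genes of regulatory T cells had promoter peaks more often than other genes. Of 33, 18 had one, or 54.5% (36.4 to 71.9; odds ratio 9.47, adjusted p = 1.1e-08, Fisher's exact test). The costimulator gene Icos had the strongest at 9.60 and 4 peaks in all. The interleukin-2 receptor genes Il2ra and Il2rb had 5.47 and 4.10. Foxp3, the lineage-defining factor of these cells, had 3 peaks, the strongest at 4.97 at 752 bp from the TSS (chromosome X, 7581235 to 7581440). By −log10 q its Intron peak came first, at 7.58 against 6.49. The checkpoint receptor gene Ctla4 had 4 peaks, the strongest by fold enrichment at 4.01 and by −log10 q the one over the TSS at 19.0, and Ikzf2 had 3, the strongest at 3.92 in an intron. Tgfb1 had 2.89, and no peak was assigned to Il10.

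The core genes' median of 3.56 over 18 genes did not pass the test against other promoter peaks (difference 0.317, adjusted p = 0.38, permutation test). By −log10 q the difference turned to −0.240 (adjusted p = 0.90, permutation test). The median of canonical targets was higher than that of core genes by 3.43 (adjusted p = 0.012, permutation test). The median of core genes was higher than the 2.82 of ribosomal proteins by 0.741 (adjusted p = 0.029), and its difference of 0.413 from receptor signalling genes did not pass the test (adjusted p = 0.44, permutation tests). These direct comparisons between lists were chosen after the data were seen. By −log10 q the order against ribosomal proteins turned, with medians of 6.64 for core genes and 6.77 for ribosomal proteins, which was not tested. Among the 455 strongest peaks, 2 of 33 core genes had a promoter peak, or 6.06% against 1.16% of other genes, and the list was not called (odds ratio 5.49, exact test, adjusted p = 0.15, from 6.4e-09 to 0.15 over the alternatives).

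Effector and tissue regulatory T cell genes had promoter peaks at 14 of 37 genes, or 37.8% (22.5 to 55.2; odds ratio 4.79, adjusted p = 7.6e-05, Fisher's exact test). S100a4 had 5.19, Rora 5.17, Gata3 4.78, Il10ra 4.74 and Batf 2.70. Irf4 had only a Downstream peak at 3.46 and Klrg1 only an Intron peak at 3.78. No peak was assigned to Prdm1, Il1rl1 or Pparg. Genes of T cell receptor signalling had promoter peaks at 16 of 32 (odds ratio 7.88, exact test, adjusted p = 2.6e-07), led by Ptprc and Ptpn6 at 5.04, Cd28 at 4.67 and Ptpn22 at 4.10. Core and receptor signalling genes did not differ by test in how often they had one (odds ratio 1.2, p = 0.81, Fisher's exact test). This comparison was chosen after the data were seen. Neither the effector nor the signalling list was called among the 455 strongest peaks, where each had 0 genes with a promoter peak (exact test, adjusted p = 1.00). Only 1.17% of other genes had one there, so counts of 0 in lists of this size show no depletion. The strong Intron peak assigned to Nfatc1, a signalling gene, does not count there.

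**Figure D3:**
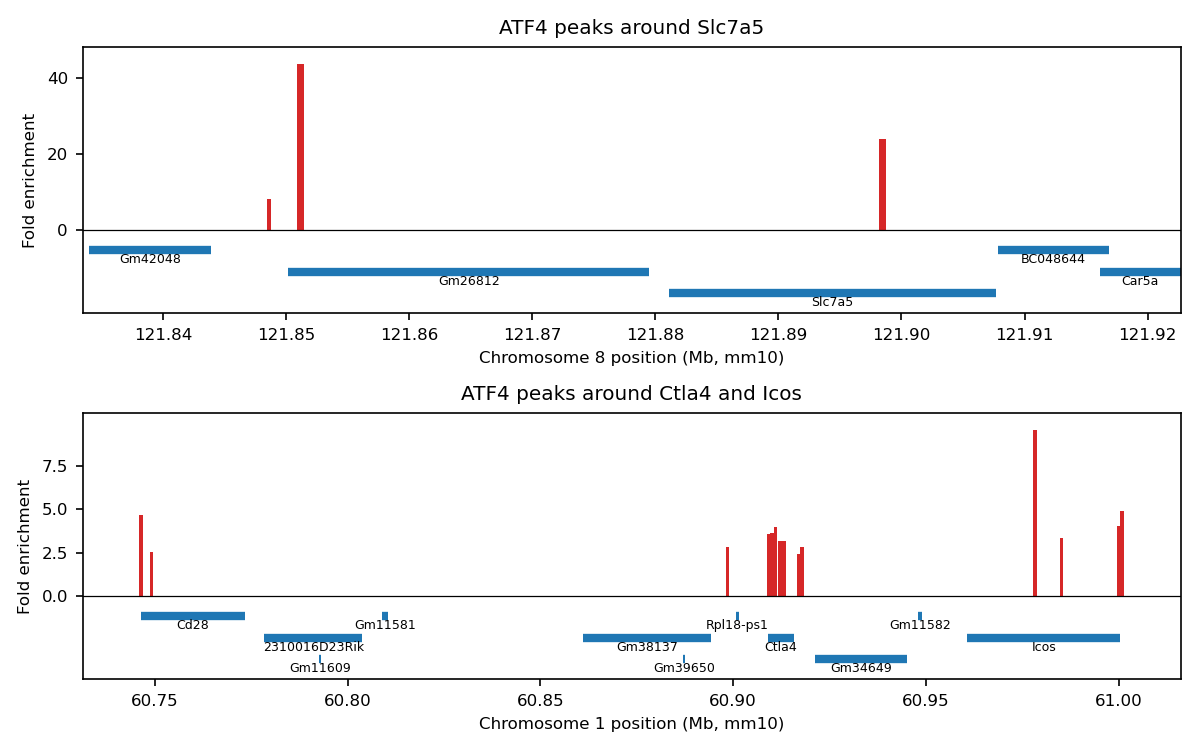
Peaks (red bars, fold enrichment) and gene spans (blue) by position in Mb on mm10, around Slc7a5 on chromosome 8 and around Ctla4 and Icos on chromosome 1. The strongest peaks were 43.8 inside the span of Gm26812, 24.0 inside Slc7a5 and 9.60 at Icos.

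Basic leucine zipper factors, the family of ATF4, had promoter peaks at 27 of 46 genes, or 58.7% (43.2 to 73.0; odds ratio 11.3, adjusted p = 1.0e-13, Fisher's exact test). After Ddit3 the strongest were Jund at 8.19, Atf5 at 7.85 and Junb at 7.51. Genes of ER stress and folding had them at 16 of 32 (odds ratio 7.88, exact test, adjusted p = 2.6e-07), among them Dnajb9 at 8.16. Cytosolic ribosomal proteins had them at 27 of 46 as well (exact test, adjusted p = 1.0e-13), with a median fold enrichment of 2.82. Among the 455 strongest peaks, 0 ribosomal protein genes and 1.17% of other genes had a promoter peak, which shows no depletion in a list of this size. Rpl3 at 5.06 and Rpl10 at 4.92 led that list.

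T cell migration genes had promoter peaks at 9 of 26 (adjusted p = 0.0037, Fisher's exact test), including S1pr4 at 5.59, S1pr1 at 5.34 and Ccr7 at 5.13. Helper T cell cytokine and lineage genes had them at 9 of 30 (exact test, adjusted p = 0.0087), including Tnf at 6.84 and Bcl6 at 4.86. Nutrient sensing had 10 of 35 (exact test, adjusted p = 0.0086), including Ddit4 at 6.77. Glycolysis and mitochondrial stress had 7 of 22 each (exact test, adjusted p = 0.014), with Ldha at 4.62 and Fgf21 at 7.62. The mitochondrial stress list lost its call when promoters were limited to 1 kb (22.7%, exact test, adjusted p = 0.13, from 0.0080 to 0.49 over the alternatives). It also lost it with genes of more than 1 list left out (adjusted p = 0.36), at a −log10 q of at least 3 (adjusted p = 0.079) and with peaks above the median fold enrichment alone (adjusted p = 0.49, exact tests). Nutrient sensing lost it with genes of more than 1 list left out (adjusted p = 0.14) and with peaks above the median alone (adjusted p = 0.070, exact tests). The helper T cell list lost it with peaks above the median alone (exact test, adjusted p = 0.13). Among the 455 strongest peaks, 7 of the 16 lists were called, which were canonical targets, tRNA synthetases, transporters, both lists of amino acid enzymes, ER stress and basic leucine zipper factors. These lists share genes, and this setting was not run without shared genes. The 4 serine and folate genes counted there, Mthfd2, Shmt2, Psat1 and Mthfd1l, are all canonical targets.

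The other lists were not called. Autophagy genes had promoter peaks at 7 of 29 (adjusted p = 0.060, Fisher's exact test), with Ulk2 at 11.8 the strongest, and passed the test with peaks above the median fold enrichment alone (adjusted p = 0.0085). Oxidative phosphorylation had 7 of 36 (exact test, adjusted p = 0.23), the proteasome 5 of 31 (adjusted p = 0.44) and insulin, leptin and lipid handling 4 of 32 (adjusted p = 0.81), with Fasn at 7.24. Among other cell types, erythroid markers had 2 of 11, with Tfrc at 8.66, and myeloid markers 2 of 20, Cebpa at 4.46 and Cd68 at 2.31. B cell markers and NK and CD8 T cell markers had 0 of 15 each, hepatocyte genes 0 of 20 and neuronal genes 0 of 22. The exact 95% intervals of these counts of 0 reach up to 21.8%, 21.8%, 16.8% and 15.4%, and the lists did not differ from the background by test (exact test, adjusted p from 0.23 to 0.44).

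**Figure D4:**
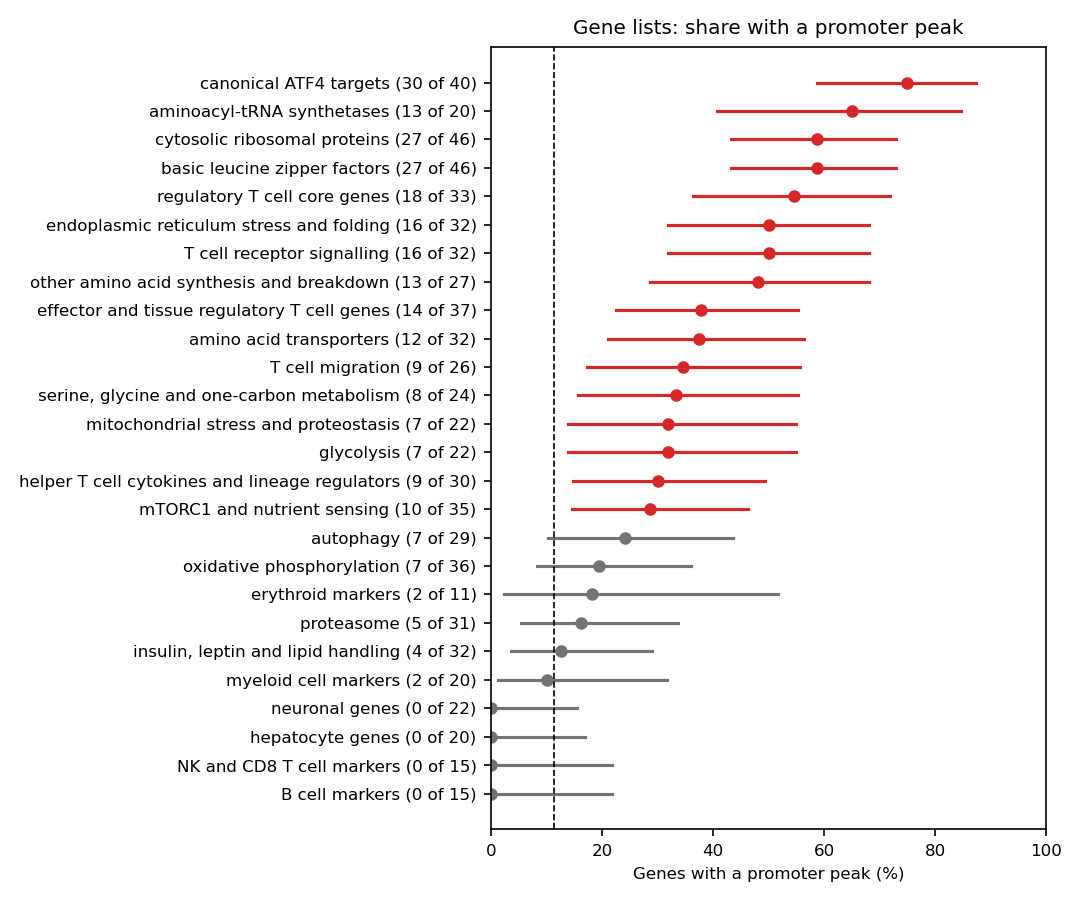
Share of each list's genes with a promoter peak (percent), with 95% exact intervals; the dashed line is the 11.3% of all background genes. Red marks the 16 of 26 lists past an adjusted p of 0.05, from canonical ATF4 targets at 75% down to nutrient sensing at 28.6%.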

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

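The tests in this part were chosen after the results were seen. These 4 kinds of peaks lay outside the genes that the list comparisons used, where a count of 0 was the reference, though the promoter and distal comparison used all peaks of those classes, such peaks among them. There were 41 promoter peaks at genes classed as snRNA, 50 at tRNA genes, 34 peaks on unplaced or unlocalised sequences and 25 peaks assigned to Mir101c near the start of chromosome 9. The Mir101c peaks had a median fold enrichment of 1.78 and a median −log10 q of 253. The highest −log10 q of the list, 7360, went with a fold enrichment of 2.54 at Gm33780. This peak was not among the 73 taken to lie over repeated sequence. An earlier test of the strength of those 73 peaks was dropped, since they had been picked for the pattern.

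The snRNA peaks were strong and broad, with a median fold enrichment of 9.49 and a median width of 865 bp, against 3.00 and 222 bp at tRNA genes. Reads shared between near-identical copies are a technical explanation that no value here decides. Tests of the snRNA peaks against other promoter peaks and against tRNA genes were dropped, since the snRNA peaks had been singled out for their strength and shared reads need not act alike at both kinds of genes. The treatment of inputs and multi-mapping reads is not given in the sources used here. No biological explanation was tested.

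Regulatory T cell core genes had promoter peaks often, and signal at active promoters or at T cell genes in general may account for this. By Fisher's exact test over 4 broadly expressed lists, core genes were not shown to differ in share from ribosomal proteins (odds ratio 0.844, adjusted p = 0.82) or glycolysis (odds ratio 2.57, adjusted p = 0.22), and had promoter peaks more often than the proteasome (odds ratio 6.24) and oxidative phosphorylation (odds ratio 4.97) lists (adjusted p = 0.0060 each). The first reading, from ribosomal proteins alone, favoured signal at active promoters and the second, from all 4 lists, went against a reworded form of it. Both were dropped, since the lists differ among themselves and promoter activity was not measured here. Core genes had a higher median fold enrichment than ribosomal proteins (difference 0.741, adjusted p = 0.029, permutation test). Their median −log10 q was lower, at 6.64 against 6.77, which was not tested. Signal at T cell genes in general cannot be told apart, with an odds ratio of 1.2 against receptor signalling genes (p = 0.81, Fisher's exact test) and exact intervals of 36.4 to 71.9% and 31.9 to 68.1% around the shares. No biological explanation was tested.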

How the results depend on the processing

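Settings for the 455 strongest peaks, peaks over repeated sequence, gene ends, a −log10 q of at least 3 for the lists, canonical targets without shared genes, and the strength of each list were chosen after seeing the data. So were the direct comparisons between lists, in share and in strength. The Promoter share moved from 74.3% to 68.9% in peaks above the median fold enrichment, 78.4% at a −log10 q of at least 3, 67.3% within 1 kb and 77.8% in the 455 strongest peaks. The promoter minus distal difference turned from −0.247 to 2.32 with −log10 q as the measure, and was −0.388 without peaks over repeated sequence. The number of enriched lists was 16 and fell to 7 in the 455 strongest peaks, where fewer peaks were tested, and was 13 to 16 in the other settings. Canonical targets stayed stronger in all 4 alternatives. In the 455 strongest peaks, 0% of glycolysis, ribosomal protein, proteasome, effector regulatory T cell and receptor signalling genes had a promoter peak. Of other genes, 1.17% had one in each comparison. At that share a count of 0 is the likeliest outcome for lists of this size, so the turned direction shows no depletion. Counting any assigned peak, myeloid markers were at 15.0% and NK and CD8 T cell markers at 13.3%, above other genes. Insulin, leptin and lipid genes were below other genes without shared genes (11.1%) and at a −log10 q of at least 3 (9.38%). The list minus other difference turned to −0.240 for regulatory T cell core genes and to 6.23 for helper T cell genes by −log10 q, and to −0.0159 for nutrient sensing without shared genes. None of these turned list results passed the test, and the cause was not tested. Across lists and settings, shares kept direction and side of the threshold 159 times. They kept the direction but lost the call 13 times, kept it and gained the call 1 time, and turned direction 9 times. Ranked by −log10 q in place of fold enrichment, the percentile of a named gene's peak moved 90 times and stayed 15 times. No paired analysis was possible because the list gives no values per replicate, and leaving out each replicate was not run for the same reason. Motif occurrence, the composite motif by strength, a CpG-rich background, divergent start sites and random placement of peaks were not run, since no genome sequence was used and the strand was at hand only for genes with an assigned peak. Depth is unknown and limits which peaks could be called.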

Other observations

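The 6 gene families, the single genes and the test without peaks over repeated sequence in this part were chosen after their values were seen. Histone genes had promoter peaks at 52 of 67 (77.6%, exact interval 65.8 to 86.9), with a median fold enrichment of 5.17 and with H4c14, H2ac18 at 8.78 and H1f2 at 8.35 the strongest. Genes of heterogeneous nuclear ribonucleoproteins had them at 12 of 21, translation initiation factors at 18 of 56, with Eif1 at 17.9, Krüppel-like factors at 8 of 17 and Gimap genes at 5 of 8 (no test is given for these families, since they were picked for having peaks). Olfactory receptor genes had them at 0 of 1106. Strong promoter peaks also lay at Cpm at 16.0, Kmt5b at 15.5, Arrdc3 at 14.9, Stk40 at 14, Polr2a at 13.5, the glucocorticoid receptor gene Nr3c1 at 13.3 and Actb at 11.8.

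The peaks at Gm26812 and in the intron of Slc7a5, the leucine transporter gene, were 46.7 kb apart. Slc7a5 had no promoter peak. Several genes held many peaks, with 8 at Hnrnpa2b1 and 7 each at Klf2 and Mir21a.

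A hypothesis on peaks in 3′ UTRs, exons and introns was that they mark signal spread along genes whose promoter also has a peak (a test chosen before its result was seen). Of 620 such peaks, 180 were assigned to a gene that also had a promoter peak, or 29.0% (25.5 to 32.8), against 33.2% (29.2 to 37.4) of 524 distal intergenic peaks (odds ratio 0.823, p = 0.14, Fisher's exact test). Without peaks over repeated sequence among the distal ones, the odds ratio was 1.18 (p = 0.24, Fisher's exact test). That setting took the distal count from 174 of 524 to 120 of 467 peaks. It leaves out genes by their number of peaks, which bears on the share itself, and was applied to distal peaks alone. Its turned sign therefore decides nothing. The outcome set down beforehand as contrary to spread, a share not above that of distal peaks, was met and was first read as excluding it. That reading was withdrawn, since it took a p over the threshold as absence, so the test leaves spread open. The assigned gene is also not always the one a peak lies in, as at Nfatc1, whose strongest Intron peak lies inside Atp9b. By class the share was 42.7% (32.3 to 53.6) for 3′ UTR, 20.6% for Exon and 27.6% for Intron peaks, without a test between classes.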
